A study of Mus musculus with 10 samples.

How the data were processed

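The series holds 10 RNA sequencing libraries of mouse splenic macrophages, 5 WT and 5 Fpr2KO, isolated with magnetic beads against F4/80. Per the labels' protocols, RNA was extracted with the Qiagen RNeasy Plus Universal Mini Kit and libraries were made from polyadenylated RNA with the NEBNext Ultra II RNA kit. The deposited file is a table of raw read counts per Ensembl gene, which the authors did not normalise: the values are whole numbers whose totals differ between libraries. The submitters' processing notes name HTSeq 0.10.0 and FastQC 0.10.1, and the genome builds mm10 and GRCm38. The aligner, the strand setting of the counting, its handling of reads that map to several places and the annotation release are not given in the sources used here. Without a known strand setting, reads of overlapping and antisense genes cannot be told apart. Groups were taken from the genotype label of each sample and replicate numbers from its title.

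Gene symbols and coordinates came from the GENCODE M21 annotation of GRCm38. It matched 52081 of the 55414 identifiers in the table, and the 3333 without a match held between 0.0873% and 0.184% of the counts of a library, so the release used for counting may have been another one, and the coordinates given are those of GENCODE M21. The table had no rows other than genes. Totals ranged from 15865820 to 19060188 counts per library, and between 21316 and 22808 genes had at least 1 count. Of 20 pairs of libraries within a group, each differed by more than sampling noise, with a chi-square per degree of freedom from 12.4 to 68.2, so all 10 libraries were kept as separate replicates.

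Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr, which left 14669, library sizes were scaled by TMM, and dispersions and quasi-likelihood fits were made with robust=TRUE. Fpr2KO was compared with WT by glmQLFTest, two-sided, with no covariate, and p-values were adjusted by the Benjamini-Hochberg method over the genes tested. The threshold was an FDR of 0.05. This fit is called the reference fit, and values without a named setting come from it. The SE of a log2 fold change was taken as its size divided by the square root of the quasi-likelihood F. The common biological coefficient of variation was 0.179. CPM values are counts scaled by the TMM-adjusted library size with cpm in edgeR, and log2 CPM values used a prior count of 2. Where a group had 0 reads, the fold change was given as a bound against a floor of 3 counts over the group. With 2 reads, it was given as a ratio with an exact 95% interval. Both cover counting error only.

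Before the data were examined, 42 gene lists with 780 genes were fixed. They cover macrophage programmes, pathways, markers of other cell types that an F4/80 isolate can hold, and signs of sample quality. 2 of the symbols were not found. The 40 lists with at least 5 genes tested were compared by camera in limma 3.58.1 on log2 CPM, with a preset inter-gene correlation of 0.01, and adjusted over lists. Beside it stand camera with an estimated correlation, fry, and an exact permutation test of the list mean over the 252 assignments of 5 and 5 libraries. The smallest p this test can give is 0.00794, and after adjustment its smallest value was 0.136, so no list passed it. At an unadjusted p under 0.05 it gave 10 lists. The level of a list in a library is the mean log2 CPM of its genes. In 5 lists the signs of the mean, the median and the test were not all alike: NADPH oxidase and antioxidant genes, fatty acid oxidation, eosinophil markers, LXR targets and glycolysis.

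Genes were named by a rule fixed before the data were examined. It takes Fpr2, then the 12 largest and 12 smallest log2 fold changes among genes past the FDR with a mean log2 CPM of at least 1. It leaves out predicted genes, pseudogenes and receptor segments, and it takes the 5 smallest p-values of a direction in which fewer than 5 genes passed. It also takes up to 4 members of each list described, by p-value, and the sex-linked genes and Nnt as checks of the samples. Shared sequence was measured as the percent of the 31-base sequences of the transcripts of a gene that occur in another gene of the same annotation. The window around Fpr2 was 5 Mb. The planned Fisher's exact test of genes past the FDR in it is not reported, because the deletion of Fpr2 fixes its outcome, and a test without Fpr2 at an unadjusted p under 0.05 was added after seeing the data.

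The fit was tested on simulated data in which 200 genes were changed before filtering and 14486 genes were tested. It recovered 68% of genes changed by 1.5-fold, 85.1% at 2-fold, 98.0% at 3-fold and 98% at 4-fold, and 9 of 180 calls (5%) were false. The simulated counts were drawn independently for each gene and library, without structure among the samples, so these rates may not hold for the data. Alternatives fixed before the data were examined were other normalisations (RLE and upper quartile), other filters, leaving out each library in turn, a replicate block, leaving out immunoglobulin, T-cell receptor, haemoglobin and mitochondrial genes, a covariate from markers of other cell types, 1 surrogate variable from sva 3.50.0, robust=FALSE, a test against a 1.2-fold change, DESeq2 1.42.0, limma voom with quality weights, and windows of 1 and 20 Mb. Leaving out Fpr2KO replicates 4 and 5, the libraries with the most genes detected, and the exact permutation of list means were added after seeing the data.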

Results

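Gene expression was measured by RNA sequencing of polyadenylated RNA in 10 libraries of mouse splenic macrophages. The cells had been enriched from spleen with magnetic beads carrying an antibody to F4/80, a surface protein of mature mouse macrophages. The libraries fell into 2 groups, 5 from wild-type C57BL/6N mice (WT) and 5 labelled as knockout for Fpr2 (Fpr2KO). Fpr2 encodes formyl peptide receptor 2, a G protein-coupled receptor of myeloid cells that binds formylated peptides, serum amyloid A and annexin A1. Each library held between 15865820 and 19060188 counts assigned to genes, and 14669 genes had enough counts to be tested. The labels do not say whether the replicates came from separate animals, so the p-values measure only the spread between these samples, which may be technical. The labels also do not give the sex of the mice or the strain background of the knockout line.

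The comparison asked how the transcriptome of splenic macrophages differed in the absence of Fpr2. Fpr2 transcripts fell from 22.97 ± 6.02 CPM (counts scaled to library size; SD, n = 5) in WT to 0 reads in every Fpr2KO library. Beyond Fpr2, 9 genes passed a false discovery rate (FDR) of 0.05 by edgeR, among them Rhox5, Pira2, Gpr137b and Tdrkh, all lower in Fpr2KO. Red pulp macrophage genes did not pass as a list, with a mean difference of 0.00 on the log2 scale (SE 0.10, n = 5 and 5). With a covariate from markers of other cell types, their mean log2 fold change was 0.16 and the list passed by camera with the preset correlation. That covariate itself correlates with genotype (r = 0.73), so this value does not by itself show a rise in Fpr2KO. Markers of erythroid cells and of the cell cycle had higher estimates in Fpr2KO, and markers of neutrophils and classical monocytes lower ones. In the reference fit by edgeR no single member of these lists passed the FDR over all genes, whereas 8 cell cycle genes passed without WT replicate 5 and members of each list did with DESeq2.

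Fpr2 (ENSMUSG00000052270) lies on the plus strand of chromosome 17 at 17887824 to 17893952 in GRCm38. The WT libraries held 1983 Fpr2 reads in all, between 19.2 and 33.6 CPM per library, and the 5 Fpr2KO libraries held none. Against a floor of 3 counts over the whole group, Fpr2 was at least 667-fold lower in Fpr2KO (FDR = 1.44e-06 by edgeR). The absence of reads over the gene model matched the genotype label in each of the 10 libraries. Which part of the gene was removed is not given in the sources used here. Of its 31-base sequences, 43.0% also occur in another annotated gene, and the annotation of Fpr3 overlaps that of Fpr2. Fpr3 had 0 reads in WT and 9 reads over 4 of the Fpr2KO libraries, too few to be tested. Fpr1, the neighbouring high-affinity receptor for formylated peptides, was measured at 36.1 ± 4.79 CPM in WT and 41.2 ± 6.18 CPM in Fpr2KO (SD, n = 5; log2 fold change 0.19, SE 0.12, FDR = 0.625 by edgeR). Fpr-rs3, Fpr-rs4, Fpr-rs6, Fpr-rs7 and Has1 had 0 reads in both groups.

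Of the 14669 genes tested, 10 passed the FDR of 0.05, with 1 higher and 9 lower in Fpr2KO, Fpr2 included. At an unadjusted p under 0.05, 716 genes were higher and 721 lower. Rhox5, a homeobox gene of the reproductive X-linked cluster, was measured at 4.99 ± 2.18 CPM in WT (SD, n = 5) and had 0 reads in Fpr2KO. This made Rhox5 at least 145-fold lower (FDR = 0.000235 by edgeR). Rhox5 lies on chromosome X at 37804842 to 37808876 and shares 0% of its 31-base sequences with another gene. Pira2, an activating receptor of the paired immunoglobulin-like receptor family on chromosome 7 (3836812 to 3845051), fell from 76.8 ± 10.1 to 36.3 ± 5.61 CPM (log2 fold change -1.08, SE 0.12, FDR = 0.00062 by edgeR). Because 96.7% of the 31-base sequences of Pira2 also occur in other genes, its count is uncertain. Gpr137b, a multi-pass protein of the lysosomal membrane encoded on chromosome 13 (13357620 to 13394014), fell from 91.4 ± 12.6 to 51.8 ± 4.82 CPM (log2 fold change -0.82, SE 0.10, FDR = 0.00221 by edgeR). Tdrkh, a Tudor domain protein of the piRNA pathway encoded on chromosome 3 (94413273 to 94434668), fell from 15.7 ± 1.91 to 9.88 ± 0.772 CPM (log2 fold change -0.67, SE 0.11, FDR = 0.0402 by edgeR), a call that ended in 7 of the 10 fits that left out 1 library. Gpr137b shares 36.4% and Tdrkh 35.5% of these sequences with other genes. All 5 Fpr2KO libraries lay below all 5 WT libraries for each of these genes.

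The other 5 genes past the FDR fell outside the rule for named genes and are named here after their values were seen. Gdf3, a ligand of the transforming growth factor beta family on chromosome 6, fell from 1.11 ± 0.405 to 0.0811 ± 0.0685 CPM (SD, n = 5; log2 fold change -3.68, FDR = 0.00592 by edgeR). Gm47283, at 90784738 to 90816464 on chromosome Y, had 1288 reads in WT and 0 in Fpr2KO, at least 433-fold lower (FDR = 0.000133 by edgeR). Gm21887, at 170009659 to 170019281 on chromosome X, had 373 reads in WT and 2 in Fpr2KO, a ratio of 188 with a 95% counting interval of 51.7 to 1560. The pseudogene Gm10693 on chromosome 7 (3860681 to 3869170), in the same cluster as Pira2, had 122 reads in WT and 0 in Fpr2KO, at least 41.0-fold lower. The lincRNA Gm42047 on chromosome 8 was the single gene that rose, from 32.7 ± 3.78 to 50.6 ± 4.36 CPM (log2 fold change 0.63, SE 0.09, FDR = 0.015 by edgeR). Between 46.8% (Gm47283) and 72.3% (Gm42047) of the 31-base sequences of the 4 genes named Gm are shared with other genes. Reads could therefore have been split or assigned either way. The calls of Gm47283 and Gm21887, and those of Pira2 and Gm10693, need not be separate events. Among genes with higher estimates that did not pass, the smallest p-values were those of Zfpm1, a cofactor of GATA1, and Tspan33, a tetraspanin. Zfpm1 had a log2 fold change of 0.75 (SE 0.13, FDR = 0.0565 by edgeR), and Tspan33 one of 0.56 (SE 0.10, FDR = 0.0845 by edgeR). Samd11 (log2 fold change 1.32), Dhrs11 (0.79) and Alad, an enzyme of heme synthesis (0.72), followed and did not pass either. Zfpm1, Tspan33, Samd11, Dhrs11 and Alad each passed without WT replicate 5, with no filter, with DESeq2 and with limma voom. Leaving out WT replicate 5 moved the count of called genes from 10 to 51, leaving out WT replicate 4 or Fpr2KO replicate 2 moved it to 26, and DESeq2 called 185. With a covariate built from markers of other cell types, 5 of the 10 calls were kept, those of Fpr2, Rhox5, Gm47283, Gm21887 and Gm10693.

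**Figure D1:**
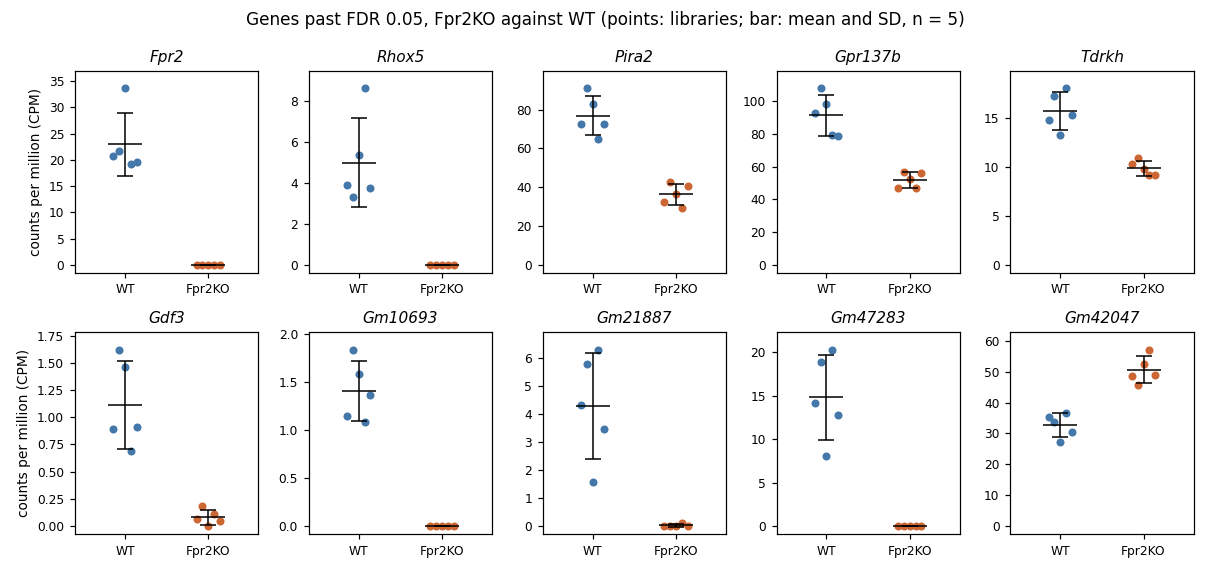
CPM of the 10 genes past an FDR of 0.05, 1 panel per gene, with the group on the x axis and CPM on a linear y axis starting near 0. Each point is a library, and the bars give the mean and SD of 5 libraries. For Fpr2, Rhox5, Gm10693 and Gm47283 every Fpr2KO library lies at 0, and for Gm42047 every Fpr2KO library lies above the WT libraries.

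Of 40 gene lists tested, 24 passed an adjusted p of 0.05 by camera with a preset inter-gene correlation of 0.01, 7 higher and 17 lower in Fpr2KO. With an estimated correlation 0 lists passed, and fry passed 1, the neutrophil list. The erythroid list was 1.73 higher on the log2 scale in Fpr2KO (SE 0.56), with 5 of 5 Fpr2KO libraries above all WT libraries. All 18 erythroid genes tested had higher estimates, 16 of them past 0.05 when adjusted over the list alone and 0 over all genes. Car1 passed over all genes without WT replicate 3, and Car1 and Gata1 did with DESeq2. The list had an adjusted p = 2.62e-16 by camera, and an adjusted p = 0.344 with an estimated correlation. Gata1, the transcription factor of erythroid and megakaryocytic cells, was measured at 4.33 ± 1.05 CPM in WT and 7.30 ± 1.22 CPM in Fpr2KO (SD, n = 5). Car1, an erythrocyte carbonic anhydrase, was measured at 3.83 ± 2.15 and 14.2 ± 4.09 CPM, and Car2 at 40.8 ± 23.8 and 113.7 ± 36.7 CPM. Klf1, the erythroid Krüppel-like factor, had a log2 fold change of 1.96 (SE 0.64). Haemoglobin transcripts made up 0.389 ± 0.17% of the counts in WT and 0.748 ± 0.22% in Fpr2KO (exact permutation p = 0.0159, two-sided, n = 5 and 5). The WT libraries were spread widely, with scores relative to their mean from -1.89 in replicate 3 to 1.04 in replicate 5.

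The cell cycle list moved with the erythroid list, 0.45 higher on the log2 scale (SE 0.14). All 32 cell cycle genes tested had higher estimates, 23 past 0.05 when adjusted over the list alone and 0 over all genes. Without WT replicate 5, 8 passed over all genes, among them Cdk1, Rrm2 and Tpx2, DESeq2 called 9, and Ccnb1 passed with no filter. Its adjusted p = 4.69e-18 by camera became an adjusted p = 0.344 with an estimated correlation. Tpx2, a spindle assembly factor, had a log2 fold change of 0.46 (SE 0.10), cyclin B1 (Ccnb1) one of 0.65 (SE 0.15), the ribonucleotide reductase subunit Rrm2 one of 0.61 (SE 0.14) and Cdk1 one of 0.73 (SE 0.18). Smaller positive differences were measured for T cell markers (0.24, SE 0.13; adjusted p = 0.403 with an estimated correlation), B cell markers (0.17, SE 0.13; adjusted p = 0.522), oxidative phosphorylation genes (0.13, SE 0.09; adjusted p = 0.534), cytosolic ribosomal proteins (0.12, SE 0.11; adjusted p = 0.665) and cholesterol biosynthesis (0.11, SE 0.06; adjusted p = 0.433), each past the threshold by camera with the preset correlation alone. Without WT replicate 2 the B cell difference was 0.094, and 0.11 without Fpr2KO replicate 4. Without Fpr2KO replicate 1 the oxidative phosphorylation difference was 0.080 and the ribosomal protein difference 0.061, the latter ranging up to 0.18 without Fpr2KO replicate 2. With the covariate from markers of other cell types, B cell markers passed in the opposite direction (-0.14, adjusted p = 0.00363 by camera). That covariate was itself built in part from the B cell markers and correlates with genotype (r = 0.73). No conclusion on B cells follows from this value.

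Neutrophil markers were lower in Fpr2KO, with a log2 difference of -0.61 (SE 0.13) and 5 of 5 Fpr2KO libraries below all WT libraries. All 17 neutrophil genes tested had lower estimates, 10 past 0.05 when adjusted over the list alone and 0 over all genes. DESeq2 called 6 over all genes, among them Mmp8, Mmp9, Lcn2 and Stfa2l1, and Mmp8 also passed with no filter and with limma voom. The list passed by camera (adjusted p = 1.39e-11) and by fry (adjusted p = 0.044), with an adjusted p = 0.18 with an estimated correlation. Across the 10 libraries, after subtracting group means, neutrophil scores went with those of the immediate early genes, a list of sample handling that shares 0 genes with it (Pearson's r = 0.84, permutation p = 0.00037, adjusted p = 0.00148 over 4 relations; Spearman's rho = 0.90, permutation p = 0.00085, adjusted p = 0.0034). Without the 2 farthest libraries r was 0.72. The collagenase Mmp8 was measured at 21.99 ± 3.16 CPM in WT and 13.2 ± 3.34 CPM in Fpr2KO, and the gelatinase Mmp9 at 132.6 ± 43.6 and 70.6 ± 17.5 CPM (SD, n = 5). Lcn2, an iron-siderophore binding protein of neutrophil granules, had a log2 fold change of -0.83 (SE 0.22), and Stfa2l1 one of -1.08 (SE 0.29). Classical monocyte markers had a difference of -0.59 (SE 0.15), with all 10 genes lower and 4 past 0.05 when adjusted over the list alone (adjusted p = 9.09e-08 by camera, adjusted p = 0.257 with an estimated correlation). Chil3, a chitinase-like protein, was measured at 104.2 ± 22.4 and 42.4 ± 15.5 CPM, and Ly6c2 at 94.0 ± 11.5 and 60.8 ± 14.2 CPM. Ly6c2 passed over all genes without Fpr2KO replicate 1, and Chil3, Hp and Ly6c2 did with DESeq2. Hp and Fn1 had log2 fold changes of -0.72 (SE 0.22) and -0.81 (SE 0.26). Platelet and megakaryocyte markers had a difference of -0.51 (SE 0.19; adjusted p = 1.03e-06 by camera, adjusted p = 0.344 with an estimated correlation). The platelet chemokine gene Ppbp was measured at 12.8 ± 3.53 CPM in WT and 6.43 ± 1.91 CPM in Fpr2KO, and Pf4 had a log2 fold change of -0.77 (SE 0.27). Ppbp passed over all genes without WT replicate 5. Basophil and mast cell markers (-0.39, SE 0.18; adjusted p = 0.372 with an estimated correlation) and nonclassical monocyte markers (-0.26, SE 0.15; adjusted p = 0.426) were lower by camera with the preset correlation. Without WT replicate 2 the basophil and mast cell difference was -0.25, and without WT replicate 3 the nonclassical monocyte difference was -0.15.

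Chemokine receptor and migration genes, a list that shares 13 members with other lists, had a difference of -0.29 (SE 0.09; adjusted p = 2.4e-06 by camera, adjusted p = 0.344 with an estimated correlation). Of its 27 genes 22 had lower estimates, and 4 passed when adjusted over the list alone. Of these, Mmp8 and Mmp9 are also in the neutrophil list, which differed by -0.61 (SE 0.13). The others were C5ar1, the receptor for complement fragment C5a (log2 fold change -0.93, SE 0.23), and the integrin subunit Itgam (-0.57, SE 0.15). Lipid mediator enzymes had a difference of -0.20 (SE 0.07; adjusted p = 0.00215 by camera, adjusted p = 0.372 with an estimated correlation). Alox12, the platelet-type lipoxygenase, was measured at 6.997 ± 1.61 CPM in WT and 3.13 ± 0.862 CPM in Fpr2KO (SD, n = 5; FDR = 0.0845 by edgeR), and passed without WT replicate 5. Alox5, which makes leukotrienes, had a log2 fold change of -0.58 (SE 0.16), and its partner Alox5ap one of -0.25 (SE 0.10). Inflammatory genes of the NF-kB response had a difference of -0.30 (SE 0.16; adjusted p = 1.03e-05 by camera, adjusted p = 0.403 with an estimated correlation). In that list the chemokine genes Ccl3, Ccl2 and Ccl4 had log2 fold changes of -0.57 (SE 0.13), -0.68 (SE 0.16) and -0.46 (SE 0.13), and the inflammasome sensor Nlrp3 one of -0.65 (SE 0.19). Ccl3 passed over all genes without WT replicate 4. The NF-kB and immediate early scores were highest in the same WT library, replicate 1 (0.27 and 0.25 relative to the WT mean). Both were lowest in WT replicate 5 (-0.33 and -0.27) and, among Fpr2KO libraries, in replicate 4 (-0.67 and -0.49). A part of sample handling in the NF-kB difference was not tested.

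2 lists fixed as signs of sample handling and RNA quality were also lower by camera. Immediate early genes, which respond to tissue dissociation, had a difference of -0.24 (SE 0.14; adjusted p = 9.09e-08 by camera, adjusted p = 0.403 with an estimated correlation). Egr1 was measured at 918.9 ± 117.6 CPM in WT and 634.4 ± 81.4 CPM in Fpr2KO, and Fos at 3613 ± 668.9 and 2737 ± 153.0 CPM (SD, n = 5). Egr1 passed over all genes without WT replicate 5. Mitochondrially encoded genes had a difference of -0.38 (SE 0.16; adjusted p = 1.54e-05 by camera, adjusted p = 0.372 with an estimated correlation). The mean scores of Fpr2KO replicates 1 and 2 lay near the WT mean, at of -0.06 and -0.05, and replicates 3, 4 and 5 at -0.49, -0.41 and -0.90. The mitochondrial share of all counts was 5.51 ± 0.48% in WT and 4.13 ± 1.104% in Fpr2KO (exact permutation p = 0.0397, two-sided, n = 5 and 5). Without Fpr2KO replicate 5 the difference of the list was -0.25. By the share of counts only replicate 2 (6.04%) resembled WT, and replicate 1 (3.99%) lay below the lowest WT library (4.83%), as did replicates 3, 4 and 5. Without Fpr2KO replicate 2, 5 mitochondrially encoded genes passed over all genes, mt-Nd1, mt-Nd2, mt-Nd4, mt-Co1 and mt-Cytb. The interferon response (-0.11, SE 0.14), lysosome (-0.06, SE 0.04), efferocytosis and scavenger receptor (-0.09, SE 0.07), complement (-0.15, SE 0.07), marginal zone macrophage (-0.14, SE 0.09) and endothelial and stromal lists (-0.14, SE 0.09) passed by camera with the preset correlation, with an adjusted p between 0.403 and 0.665 with an estimated correlation. Without Fpr2KO replicate 4 the differences were -0.0060 for interferon response, -0.036 for lysosome, -0.049 for efferocytosis and -0.076 for marginal zone macrophages. The interferon difference was -0.044 without WT replicate 4 and -0.19 without Fpr2KO replicate 2, and that of efferocytosis -0.043 without WT replicate 3. A list of 5 genes that differ between C57BL/6 substrains had a difference of -0.19 (SE 0.07), all 5 with lower estimates. It passed by camera with the preset correlation (adjusted p = 0.0251) and had an adjusted p = 0.372 with an estimated correlation. Of the Fpr2KO libraries, 4 lay below all WT libraries.

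**Figure D2:**
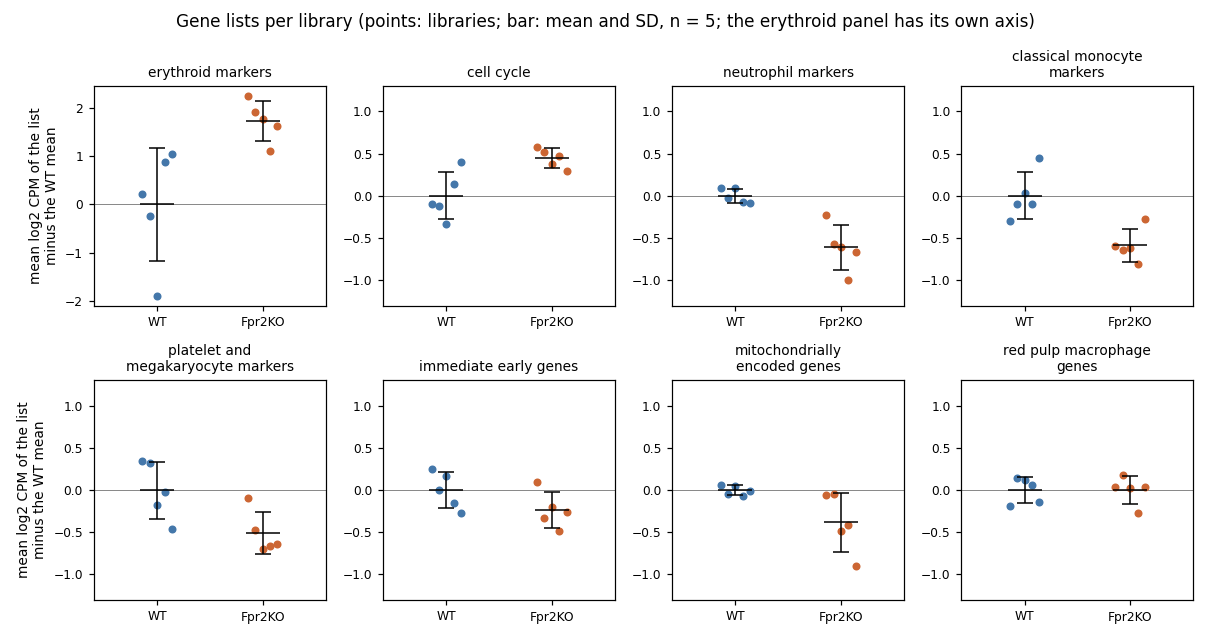
Mean log2 CPM of 8 gene lists in each library, minus the WT mean, with the group on the x axis and the log2 difference on the y axis. Points are libraries and bars the mean and SD of 5 libraries. Erythroid scores reach from -1.89 to 1.04 in WT and lie above 1.04 in all 5 Fpr2KO libraries, neutrophil scores of Fpr2KO lie below all WT libraries, and red pulp macrophage scores overlap.

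The red pulp macrophage list of 24 genes held 10 higher and 14 lower estimates, and neither camera (adjusted p = 0.733) nor an exact permutation of its mean (p = 1, two-sided, n = 5 and 5) separated the groups. With the covariate from markers of other cell types, its mean log2 fold change was 0.16 (adjusted p = 0.000681 by camera with the preset correlation). That covariate correlates with genotype (r = 0.73), so this value does not by itself show a rise in Fpr2KO. Cd163, the scavenger receptor for haemoglobin, was measured at 278.7 ± 39.8 CPM in WT and 382.9 ± 22.995 CPM in Fpr2KO (SD, n = 5; log2 fold change 0.46, SE 0.10, FDR = 0.135 by edgeR), with all 5 Fpr2KO libraries above all WT libraries. Cd163 was the 1 red pulp gene that passed when adjusted over the list alone, and it passed over all genes without WT replicate 5. Clec12a, Treml4 and Mertk had log2 fold changes of -0.18 (SE 0.11), -0.13 (SE 0.10) and -0.12 (SE 0.11). In the heme and iron handling list (0.03, SE 0.06; camera adjusted p = 0.569), the heme-responsive repressor Bach1 had a log2 fold change of -0.33 (SE 0.10) and the biliverdin reductase Blvrb one of 0.30 (SE 0.13). Lists of Fpr2 ligands and partners (-0.15, SE 0.11), alternative activation (-0.13, SE 0.07) and class II antigen presentation (0.06, SE 0.05) did not pass by camera, with an adjusted p of 0.114, 0.126 and 0.168. The score of Fpr2 ligands and partners was lowest in Fpr2KO replicate 2, at -0.41 relative to the WT mean. The class II difference was 0.038 without WT replicate 5 and 0.090 without Fpr2KO replicate 2.

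**Figure D3:**
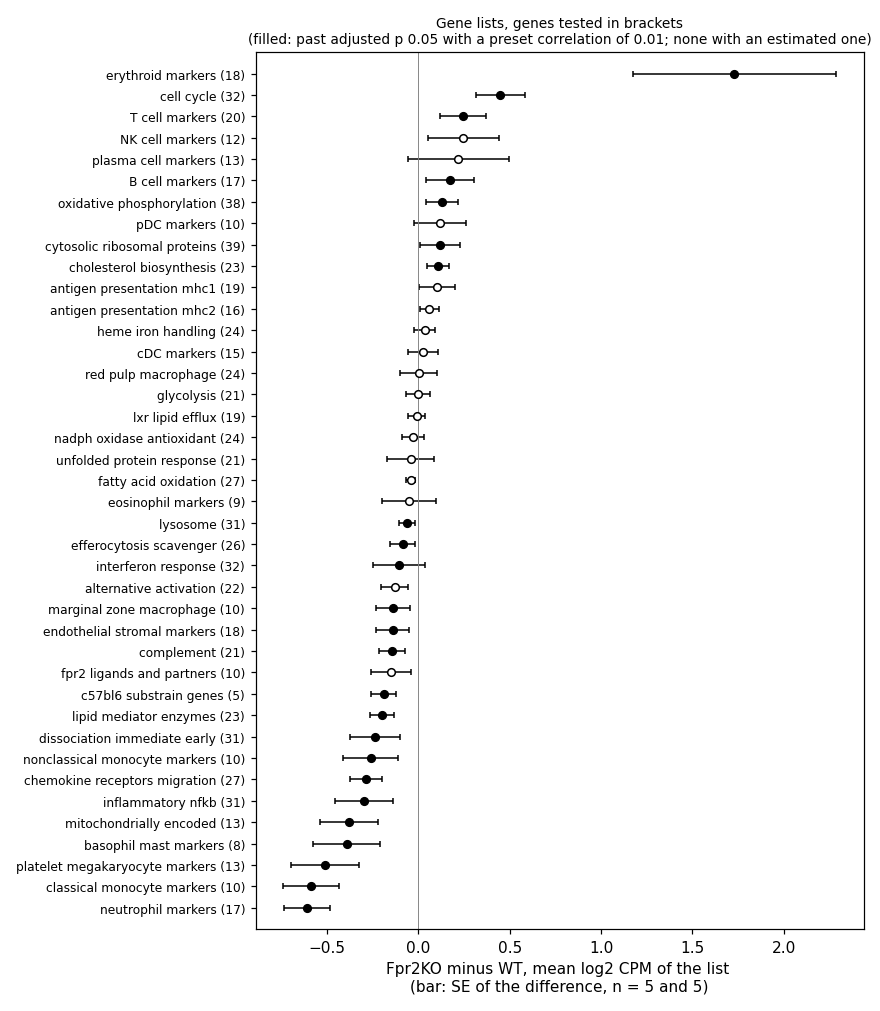
Difference between Fpr2KO and WT in the mean log2 CPM of each of 40 gene lists, on a linear x axis with lists as rows and the number of genes tested in brackets. Bars are the SE of the difference over 5 and 5 libraries, and filled points passed an adjusted p of 0.05 by camera with the preset correlation. Differences run from -0.61 for neutrophil markers to 1.73 for erythroid markers.

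Around the targeted locus, 61 genes within 5 Mb of Fpr2 on chromosome 17 were tested and 0 passed the FDR by edgeR other than Fpr2 itself. Leaving out Fpr2, 3.33% of the genes in the window had an unadjusted p under 0.05, against 9.83% elsewhere (Fisher's exact test, two-sided p = 0.123, added after seeing the data). As checks of the samples, the Y-linked genes Ddx3y (153.9 ± 18.01 CPM in WT and 150.4 ± 32.1 CPM in Fpr2KO) and Kdm5d (50.7 ± 4.51 and 50.2 ± 3.76 CPM) were read in all libraries. Nnt was measured at 2.18 ± 0.31 CPM in WT and 1.97 ± 0.613 CPM in Fpr2KO (SD, n = 5).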

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

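Tests of passenger DNA around Fpr2, of the summed count of Pira2 and its relatives, of a lower share of macrophages, of sample handling, and of library quality for the neutrophil and monocyte lists taken singly were chosen after their results had been seen. In 220 groups of 5 libraries, 8 had 1 library far from the other 4, where chance gives about 11. The log2 CPM of Fpr2 in WT replicate 3 was 5.08, above the next WT library at 4.44. Among the Fpr2KO libraries, Gm21887 had reads in replicate 4 alone, at a log2 CPM of -2.16. Alox5 in Fpr2KO replicate 5 lay at 4.99, with the next library at 4.47. Relative to the WT mean, the glycolysis score of Fpr2KO replicate 2 was -0.24, the NF-kB inflammatory score of Fpr2KO replicate 4 was -0.67 and the NK cell score of WT replicate 3 was -0.68. The mitochondrial share was 6.04% in Fpr2KO replicate 2, with the next Fpr2KO library at 3.99%. WT replicate 5 had 21735 genes with a count, and the next WT library 21809.

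The first pattern is the set of 9 genes other than Fpr2 past the FDR. Of these 9, 0 lie on chromosome 17, which argues against passenger DNA flanking Fpr2. In 7 of the 9 (77.8%), at least 20% of the 31-base sequences are shared with another gene. Of the other genes tested, 17.4% reached that level (Fisher's exact test, two-sided p = 0.000128). Shared reads may therefore contribute for those 7, but not for Rhox5 (0%) or Gdf3 (2.97%). The measure also counts overlapping annotations of the same locus, so it does not by itself show near-identical copies. The test takes the 9 genes as separate, which Pira2 and Gm10693, or Gm47283 and Gm21887, need not be. The summed count of Pira2 and its relatives, 10 genes in all, differed by -0.23 on the log2 scale (SE 0.10, exact permutation p = 0.0635). Of these relatives Gm14548 had an estimate of 0.49. How reads that map to several places were counted is not known, so a shift of reads need not leave the sum unchanged. Whether such a shift accounts for the fall of Pira2 therefore cannot be told. Haplotypes that differ between the lines cannot be told apart from effects of the deletion, and the background of the knockout line is not given. Of 161 genes within 1 Mb of the 9, 10.6% had an unadjusted p under 0.05, against 9.74% elsewhere (Fisher's exact test, p = 0.689). This test pools all the loci, so a haplotype at a single locus could go unseen. The list of genes that differ between C57BL/6 substrains was lower in Fpr2KO (-0.19, SE 0.07), which bears on the background but does not settle it.

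The second pattern is the higher erythroid and cell cycle lists in Fpr2KO. A lower share of macrophages that raised every other cell type alike would raise neutrophil markers too. The neutrophil list, at -0.61 (SE 0.13), moved against the erythroid list, at 1.73 (SE 0.56; 18 of 19 genes tested, 1 also in another list). This argues against such an even rise only. A lower share of macrophages through some cell types alone is left open, as the test was chosen after the pattern was seen. With the erythroid score as covariate, the cell cycle difference was 21.6% of the unadjusted one (0.10, SE 0.12, against 0.45, SE 0.14). The erythroid score itself separates the groups, with 5 of 5 Fpr2KO libraries above all WT libraries. This covariate would therefore also take up a cell cycle difference that came with the genotype, and cannot decide the source. Transcripts of dividing erythroid precursors are a candidate source of the cell cycle difference. Across the 10 libraries, after subtracting group means, the scores correlated with Pearson's r = 0.84 (permutation p = 0.00395) and Spearman's rho = 0.82 (permutation p = 0.00584), and r = 0.59 without the 2 farthest libraries. Beads against F4/80 should leave out erythroid cells, yet Hbb-bs stood at 2345 CPM in WT and 4379 CPM in Fpr2KO, so cells attached to or taken up by macrophages, carry-over and a change in the spleen itself all stay open, as does the genotype.

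The third pattern is the lower neutrophil and classical monocyte lists in Fpr2KO. With the mitochondrial score as covariate, a measure of library quality, the difference of the 2 lists together stayed at 99.9% of the unadjusted one (-0.60, SE 0.14; 4 of the neutrophil and 3 of the monocyte genes are also in other lists), as an average of 77.0% for the neutrophil list (-0.47, SE 0.16) and 124% for the monocyte list (-0.73, SE 0.20). With the immediate early score, a measure of sample handling that went with the neutrophil score within groups (r = 0.84, permutation p = 0.00037), they stood at 69.9% (-0.43, SE 0.09) and 113% (-0.67, SE 0.18). For the monocyte list these values argue against library quality and sample handling only as far as the 2 scores measure them. For the neutrophil list neither can be told apart at 5 libraries per group, because such scores measure quality and handling only in part. The mitochondrial share of counts was not used as a covariate for either list. It put Fpr2KO replicate 1 (3.99%) below the lowest WT library (4.83%), whereas the score put that library near the WT mean (-0.06). Library quality beyond the score therefore stays open. 17 other neutrophil-restricted genes that are in none of the lists were chosen after the pattern but before their own values were seen. Only 10 had enough counts to be tested, some with few reads, such as Ceacam10 (0.73 CPM in WT and 0.49 CPM in Fpr2KO). Of these 10, 9 had lower estimates, and the mean of the 10 differed by -0.49 (SE 0.18, exact permutation p = 0.0476). Fewer neutrophils in the Fpr2KO isolates would give this, although beads against F4/80 should leave neutrophils out. The abundant S100a8 (162.6 and 99.5 CPM) and S100a9 (214.7 and 153.0 CPM in WT and Fpr2KO) had lower estimates too. S100a8 is itself in the neutrophil list, so it adds no separate evidence. Lower expression per cell and, for the monocyte list, fewer monocytes were not tested and stay open, as does the genotype.

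For the counts of genes and lists past the threshold, fewer than 1 in 20 splits of the libraries gave as many as the real one. Chance assignment is not excluded by this, since the deletion fixes the call of Fpr2 in advance and other splits gave higher counts. The 1437 genes at an unadjusted p under 0.05 were a number that 11 of 100 splits reached. Of 100 splits of the 10 libraries into 5 and 5, 3 gave at least as many genes as the real 10, the real one included, and the highest other split gave 1428. That split sets WT replicate 4 with 4 Fpr2KO libraries and Fpr2KO replicate 2 with 4 WT libraries, as the first principal component does (29.9% of the variance; scores 6.39 and -15.9). It points to a structure of the samples that yields more calls than genotype. The mitochondrial share of counts divides the libraries in the same way. It ran from 5.28% to 6.09% on the side of Fpr2KO replicate 2 and from 3.22% to 4.83% on the other. The structure does not come from swapped labels, since WT replicate 4 had 337 Fpr2 reads and Fpr2KO replicate 2 had 0. For gene lists, 2 of the 100 splits gave at least the real 24, and the highest other gave 31. The other splits gave a median of 12 lists past camera and 0 genes, so a list past camera with the preset correlation is not by itself a sign of genotype.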

How the results depend on the processing

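Fpr2 kept its direction and passed under every alternative run for it. Of the 10 called genes, the count stayed within 1.5 times under RLE, upper quartile, at least 1 CPM in 5 libraries, removal of immunoglobulin, T-cell receptor, haemoglobin and mitochondrial genes, 1 surrogate variable, robust=FALSE and the 1.2-fold test (8 to 11 genes). It was 62 with no filter (26 higher, 36 lower), 185 with DESeq2 (86 and 99), 50 with limma voom (21 and 29) and 5 with the covariate from other cell markers, which itself correlates with genotype (r = 0.73). Each of these settings but the covariate kept all 10 calls, and the causes were not tested. Leaving out 1 library gave 8 to 51 genes: 51 without WT replicate 5, 26 without WT replicate 4 and 26 without Fpr2KO replicate 2. Tdrkh lost its call without WT replicates 1, 2 or 4 or Fpr2KO replicates 1, 3, 4 or 5, and Gm42047 without WT replicate 2 or Fpr2KO replicate 3. Tdrkh also lost it under upper quartile, 1 surrogate variable, robust=FALSE and the 1.2-fold test, Gm42047 under the surrogate variable and the 1.2-fold test, Gdf3 at 1 CPM in 5 libraries, and all 3 with the marker covariate and without Fpr2KO replicates 4 and 5. Zfpm1 passed without WT replicates 1, 4 or 5 or Fpr2KO replicate 2, without immunoglobulin, T-cell receptor, haemoglobin and mitochondrial genes, and with no filter, the replicate block, DESeq2 and limma voom. Cd163, Alox12 and Egr1 passed with no filter, DESeq2 and limma voom too, Ccl3 with no filter and DESeq2, and C5ar1, Itgam, Alox5 and Ppbp with DESeq2. Without Fpr2KO replicates 4 and 5, chosen after seeing the data, 9 genes passed, 7 of them among the 10. The replicate block gave 64 genes (13 higher, 51 lower), 5 of them neutrophil and 1 a classical monocyte marker. Whether the numbers pair the samples is not clear. Same-numbered libraries correlated from -0.24 to 0.29, and 2 of 5 correlated best with their own number.

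Gene lists past camera numbered 18 to 25 when 1 library was left out, 11 with the marker covariate (6 higher, 5 lower), 0 with an estimated correlation, 1 with fry and 0 with the exact permutation, which was added after seeing the data. With the marker covariate the direction turned for red pulp macrophage genes (0.16, adjusted p = 0.000681 by camera). B cell markers turned too (-0.14, adjusted p = 0.00363 by camera, so past the threshold in the opposite direction). So did T cell markers (-0.063), nonclassical monocyte markers (0.12), efferocytosis (0.086), lysosome (0.031) and complement (0.0011). By the test though not by the mean, ribosomal proteins (0.021) and lipid mediator enzymes (-0.042) turned. Of single genes, Clec12a (0.10), Treml4 (0.073), Lrp1 (0.033) and Alox5ap (0.012) turned. The covariate was built in part from the B cell, T cell and nonclassical monocyte markers and correlates with genotype. These turns therefore cannot be read as effects of genotype. The red pulp mean, near 0, also turned with 1 surrogate variable (0.054), without Fpr2KO replicates 4 and 5 (0.066; interferon response 0.056) and when 1 library was left out (-0.056 to 0.062; WT replicates 2 and 3, Fpr2KO replicate 4). The heme and iron list ranged from 0.0078 to 0.079, its test turning without Fpr2KO replicate 2. Within 20 Mb of Fpr2, 1 of 473 genes passed, Fpr2 itself, and 0 others passed within 1, 5 or 20 Mb. Without Fpr2, an unadjusted p under 0.05 held for 10.6% within 20 Mb and 9.77% elsewhere (Fisher's exact p = 0.53, added after seeing the data). The ribosomal, lysosome, interferon, cholesterol, efferocytosis, endothelial, substrain, complement and marginal zone lists each lost their call without at least 1 library, most often Fpr2KO replicate 4. Over all settings, 126 gene or list values lost their call, 90 gained one and 1712 stayed as they were. Depth limits the genes with few reads, such as Gdf3 (97 reads in WT, 7 in Fpr2KO).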

Other observations

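Genes of heme synthesis, a list chosen after seeing the data, had higher estimates in Fpr2KO for 12 of 13 members. Leaving out 4 members whose values had been seen, the other 9 had a mean difference of 0.42 on the log2 scale (SE 0.10, exact permutation p = 0.00794, the smallest this test can give). Fech, which inserts the iron, was measured at 65.0 CPM in WT and 99.7 CPM in Fpr2KO. Alas1, the form of the first enzyme that most tissues use, had a log2 fold change of -0.07 (SE 0.08), while the erythroid form Alas2, also a member of the erythroid list, had one of 0.94 (SE 0.34). None of these genes passed the FDR over all genes in the reference fit by edgeR, while Alad, Cpox and Urod passed with no filter, with DESeq2 and with limma voom, and Alad and Cpox without WT replicate 5.

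Other genes, named after their values were seen, passed when adjusted over their list alone and did not pass over all genes in the reference fit. Over all genes, Igha, Gsr and Siglec1 passed with DESeq2, Gsr also with no filter and with limma voom, and Siglec1 also with the replicate block. Igha, the constant region of immunoglobulin A, was measured at 657.7 ± 335.4 CPM in WT and 2290 ± 696.2 CPM in Fpr2KO (SD, n = 5), although the whole plasma cell list differed by 0.22 (SE 0.27). The glutathione reductase gene Gsr had a log2 fold change of -0.55 (SE 0.11), and Siglec1, the sialic acid receptor of metallophilic macrophages, one of -0.63 (SE 0.15). At the end of chromosome X, next to Gm21887, Mid1 had a log2 fold change of -0.62 (SE 0.20) and did not pass.

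Rhox5, Tdrkh and Gdf3 passed the FDR, and Rnf17 (log2 fold change -1.47) and Xlr3b (-1.45), which did not in the reference fit but did without Fpr2KO replicate 2, with DESeq2 and with limma voom, are also known for germ cell or early embryonic expression. One hypothesis was that germline-restricted genes may be lower as a class. Xlr3a (-0.92, SE 0.46) was left out as well, as its value had been seen. Of 50 other such genes chosen, 15 had enough counts to be tested. These 15 differed by -0.27 (SE 0.13, exact permutation p = 0.0873), with 12 of 15 lower, which leaves this hypothesis open. Another was that X-linked genes may be lower as a class, since Rhox5, Xlr3b, Map3k15 and Atp7a lie on chromosome X: with these left out, X-linked genes made up 3.35% of the genes lower at an unadjusted p under 0.05 and 3.04% of the rest (Fisher's exact test, p = 0.579), which leaves this open too.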
